A study of Mus musculus with 4 samples.

How the data were processed

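RNA sequencing of spinal cord from mice at postnatal day 8 was available as 4 libraries, 2 from control animals and 2 from conditional knockout (cKO) animals. Per the labels' protocols, cords were frozen, total RNA was extracted with Trizol, and libraries were made with a TruSeq RNA kit. The strain background is given as mixed. Groups and replicate numbers were taken from the sample titles. The labels call the libraries of a group replicates and do not say whether each came from a separate animal. The p-values therefore rest on the spread between these libraries, pooled in part over all genes.

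The deposited tables hold FPKM, fragments per kilobase of transcript and mapped depth, in the layout that Cufflinks writes, per the file headers. CASAVA, TopHat, Cufflinks and Cuffdiff and the genome build mm9 are named in the submitters' processing notes, with no versions. Each table also gives coverage, a signal of mean depth per base of the transcript, per the file headers. Each of the 28107 rows is a RefSeq transcript at a locus, and together they cover 22096 gene symbols. The row order differs between the tables, so rows were joined on transcript, symbol, locus and length. A status other than OK in any library was found in 315 rows, which were left out of the tests. Confidence bounds for FPKM are not in the columns used here, so a planned count of genes beyond those bounds was not made. Symbols are printed as in the files, except that older symbols of list members were matched through their transcript accession. Of all rows, 97.6% matched the reference table of RefSeq genes by accession, and no coordinate was taken from that table, since its assembly is not mm9. Coordinates are those of the deposited tables on mm9, with starts raised by 1 to count from 1.

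Read totals are not given in the sources used here. The ratio of coverage to FPKM is constant within a library and gives its relative depth, which was 2.07 for control 1, 1.0 for control 2, 2.22 for cKO 1 and 3.19 for cKO 2, relative to the shallowest library. Coverage times length summed to 1218, 582, 1314 and 1818 megabases in the same order. The median moderated standard deviation within groups was 0.156 on the log2 scale for gene sums.

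FPKM was transformed as log2(FPKM + 1). Transcripts with a mean FPKM of at least 1 over the 4 libraries were tested with limma 3.58.1 in R 4.3.3 by a linear model of genotype with empirical Bayes moderation and a mean-variance trend, and p-values were adjusted by the Benjamini-Hochberg method at a threshold of 0.05. A count model was not used because the values are FPKM. Beside this test, a rule of size counted transcripts for which both cKO libraries lay beyond both control libraries by at least 1.5-fold. This design was fixed before the data were examined. Transcript isoforms of a gene share reads, and transcripts under 300 bases varied far more than longer ones. After the data were seen, a second fit was therefore made on FPKM summed over the transcripts of at least 300 bases of each gene symbol, called gene sums below. Summing all transcripts and testing the longer transcripts alone were tried as well and gave far fewer calls, and the gene sums were adopted after these counts had been seen. In the report, rose and fell refer to the adjusted p of the gene sums unless transcripts are named. Their spread had 36.3 prior against 2 residual degrees of freedom (2.71 prior for transcripts), so it is mostly pooled over genes. A gene can thus pass although its own libraries differ widely, as Eif2s3y did at 0.35 and 20.4 FPKM in cKO 1 and cKO 2 (limma adjusted p = 0.00128).

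Before the data were examined, 26 gene lists were fixed, of which 22 were tested on the transcripts with camera at a preset correlation of 0.01, with adjustment over the lists. The other 4 are the proposed CHD7 targets, drawn up from knowledge of the study, the sex-linked genes, and the skeletal muscle and mitochondrial genome lists, with 2 and no measured members. For each list symbol the row with the highest mean FPKM was used. The same test with an estimated correlation and fry were run beside it. With an estimated correlation, camera has only the 2 residual degrees of freedom. No list passed it, with a lowest adjusted p of 0.601 on transcripts and 0.532 on gene sums, so it does not tell the lists apart. The genes named were Chd7, up to 12 transcripts per direction with the largest change among those past the threshold whose groups did not overlap, filled up from the size rule by the smallest p, up to 4 members of each list with the smallest p, and all members of the lists of proposed CHD7 targets and sex-linked genes. Predicted genes and short RNAs were skipped in the ranking. The same ranking was applied to the gene sums after the data were seen, and other genes are named where a count is spelled out. Some genes that these rules select are not reported here.

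The script was tested on simulated values with the means and spreads of these libraries, in which 200 rows were changed by known folds. With the moderated spread, in the simulated transcripts, cKO against control, 1.7% of the rows changed 1.5-fold were called, 36.2% of those changed 2-fold and 87.7% of those changed 4-fold, among 15494 rows. In the simulated gene sums, 56.3% of those changed 1.5-fold were called, and all of the 68 and 61 genes changed 2-fold and 4-fold, among 12913 genes. Unchanged rows called were 12 and 16. With the raw spread of each row, run first and replaced after it recovered less, 0%, 0% and 46.6% of the changed transcripts were called at these folds, and 0%, 44.1% and 83.6% of the changed gene sums, with 2 unchanged rows called in each. Noise was drawn independently for each row, so differences between libraries that many genes share are not covered. For gene sums the prior degrees of freedom of the spread were infinite with the moderated spread and 1.95 with the raw spread, against 36.3 in the data. Alternatives covered the pseudocount, the filter on low values, the scaling between libraries, the moderation, summing over transcripts, a replicate block, the thresholds and leaving out each library. Figures were drawn with matplotlib 3.10.9 from tables made with pandas 2.3.3 in Python 3.11.15.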

Results

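Transcript levels were measured in whole spinal cord at postnatal day 8 in 2 control and 2 cKO libraries. Control animals carried a floxed and an unfloxed Chd7 allele with Cre recombinase driven from Olig1, a gene of the oligodendrocyte lineage, and cKO animals carried floxed alleles only with the same Cre. Chd7 encodes a chromatin remodeler of the CHD family. The series concerns the part that CHD7 and the transcription factor Sox10 play in the timing of myelination. Relative sequencing depth was lowest in control 2 (1.0) and highest in cKO 2 (3.19), with control 1 at 2.07 and cKO 1 at 2.22. Across gene sums, the log2 values of the 2 control libraries correlated at 0.986 and those of the 2 cKO libraries at 0.990. Correlations between the groups, across genes, ran from 0.967 to 0.980. cKO 1 lay farther from the controls than cKO 2 did, with 1806 and 1370 genes differing by at least 1.5-fold from control 1 and control 2, against 694 and 778 for cKO 2.

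Chd7 itself (chromosome 4, 8618068 to 8793956 on mm9, 1 transcript) was measured at 3.52 and 3.12 FPKM in the control libraries and at 2.53 and 3.38 FPKM in the cKO libraries. The means were 3.32 ± 0.279 and 2.95 ± 0.607 FPKM (SD, n = 2 each), and the log2 fold change of -0.13 ± 0.18 (SE) did not pass the limma test (adjusted p = 0.731). The floxed part of the gene is not given in the labels, the control is heterozygous, and the cord holds many cells outside the Olig1 lineage, so this value checks the genotypes little.

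Genes of the myelin sheath were lower in cKO cords. Of 31 measured myelin genes, 27 fell in the gene sums and none rose, with a median log2 fold change of -1.03, which is 2.04-fold lower. Opalin, a membrane protein of myelinating oligodendrocytes, was at 22.6 ± 1.30 FPKM in control and 4.75 ± 1.54 in cKO (SD, n = 2 each), a log2 fold change of -2.06 ± 0.16 (SE, adjusted p = 4.53e-12). At the same fold change it did not pass in the limma fit of transcripts (adjusted p = 0.111). Mog, a protein of the outer myelin surface, went from 242 ± 9.70 to 101.1 ± 22.4 FPKM, and Aspa, the aspartoacylase of oligodendrocytes, from 21.7 ± 1.31 to 9.35 ± 0.614 FPKM. Adamts4, a metalloprotease, went from 48.6 ± 1.66 to 15.9 ± 4.62 FPKM. Mbp, at 9800 ± 1423 and 5260 ± 1449 FPKM, had a log2 fold change of -0.92 ± 0.48 that did not pass (adjusted p = 0.234), although both cKO libraries lay below both controls. Gal3st1, Qdpr and Tppp3 did not pass either. Mbp passed in limma without the mean-variance trend (adjusted p = 8.71e-04) and did not with a replicate block (adjusted p = 0.629), at the same fold change. Quantile scaling, which gives genes of equal rank the same value, set its log2 fold change to 0. Of the gene sums, 28 fell adjusted over the list alone.

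In the transcript fit fixed beforehand, none of the 31 myelin transcripts passed over all transcripts and 24 passed adjusted over the list alone, all lower. The list as a set was lower by camera (median -1.02, adjusted p = 4.65e-16). This call was lost with an estimated correlation (adjusted p = 0.601), a test on 2 residual degrees of freedom that no list passed. The median of the gene sums relative to the control mean was -1.26 in cKO 1 and -0.75 in cKO 2. Without cKO 1, 14 of the gene sums fell instead of 27, and without control 2, 17 fell. With no filter on low values, 2 fell.

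**Figure D1:**
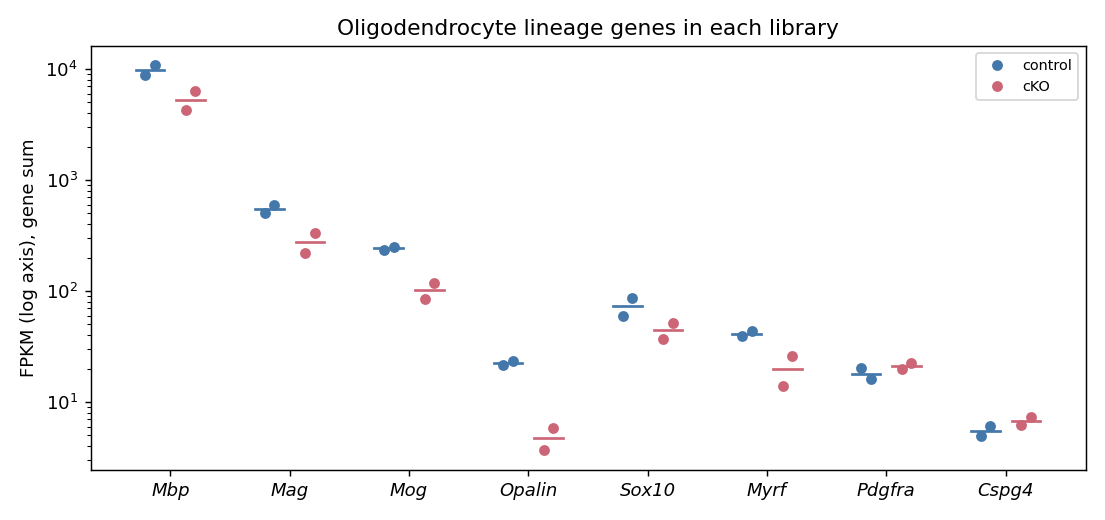
FPKM per library (log axis, gene sums) for 8 genes of the oligodendrocyte lineage, chosen for the plot after their values were seen, with control libraries in blue, cKO libraries in red and bars at the group means. For Mbp, Mag, Mog, Opalin, Sox10 and Myrf both cKO points lie below both control points, while Pdgfra and Cspg4 overlap between the groups or lie slightly higher in cKO.

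Genes of newly formed oligodendrocytes moved with the myelin genes. Of 19 measured members, 11 fell and none rose in the gene sums, with a median of -0.70. Gpr17, a receptor of cells at the start of differentiation, went from 111 ± 4.81 to 36.2 ± 4.64 FPKM (SD, n = 2 each; log2 fold change -1.60 ± 0.17, adjusted p = 2.37e-08). The noncoding transcript 9630013A20Rik went from 38.7 ± 8.08 to 10.5 ± 2.66 FPKM, and Bcas1 from 155 ± 19.5 to 71.9 ± 12.8 FPKM. Rras2, a small GTPase, went from 28.6 ± 0.807 to 16.4 ± 1.25 FPKM. Without cKO 1, 7 of these gene sums fell, with a median of -0.46, and with no filter 2 fell. None of the 19 transcripts passed over all transcripts and 10 did so adjusted over the list alone. Camera placed the list lower (adjusted p = 2.04e-09), and with an estimated correlation the call was lost (adjusted p = 0.601).

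Genes of oligodendrocyte precursors did not move as a group. Among 20 measured members the median log2 fold change was 0.10, 3 rose and 3 fell. Kcnip3 rose from 21.9 ± 2.25 to 44.6 ± 2.82 FPKM (SD, n = 2 each; adjusted p = 3.14e-05), and Lppr1 and Cacng4 rose by 0.51 and 0.49 on the log2 scale. Neu4, a sialidase, fell from 9.29 ± 1.23 to 3.52 ± 0.501 FPKM (log2 fold change -1.19 ± 0.15), and the matrix genes Vcan and Tnr fell by 0.83 and 0.81. Pdgfra, the growth factor receptor of precursors, was at 18.1 ± 2.83 FPKM in control and 21.1 ± 2.07 in cKO (adjusted p = 0.425). In the gene sums 6 rose and 4 fell adjusted over the list alone. Without cKO 1, 1 rose and 1 fell, under TPM scaling or without control 2, 1 rose, and none passed with no filter. The set test on transcripts did not pass (adjusted p = 0.382).

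Regulators of oligodendrocyte differentiation were lower. Of 20 members, 11 fell and none rose in the gene sums, with a median of -0.58. Erbb3, a neuregulin receptor, went from 5.74 ± 0.356 to 1.65 ± 0.639 FPKM (SD, n = 2 each; log2 fold change -1.37 ± 0.16, adjusted p = 1.29e-07). Gpr37 went from 41.3 ± 0.583 to 21.4 ± 3.76 FPKM, the transcription factor Nkx2-2 from 13.8 ± 3.59 to 7.92 ± 0.0118, and Zeb2 from 16.98 ± 1.13 to 7.65 ± 2.19. Olig1, Olig2, Sox8, Sox10, Yy1, Prrx1 and Myrf also fell. Of the gene sums 13 fell, and of the transcripts 8, adjusted over the list alone. Without control 2, 5 gene sums fell instead of 11, without cKO 1, 6 fell, and with no filter none did. Camera on transcripts gave an adjusted p of 1.44e-04 at the preset correlation and an adjusted p = 0.601 with an estimated correlation.

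Of 18 genes listed beforehand as inhibitors of differentiation, 5 fell and 2 rose, with a median of -0.22. Whether each member acts as an inhibitor in this tissue was not tested, and the list may hold members with the opposite role. A lower median of the list therefore does not show that inhibition was lower. Bmp4 went from 9.47 ± 1.38 to 3.46 ± 0.153 FPKM (SD, n = 2 each; log2 fold change -1.22 ± 0.15), and Smad7, Zfp365, Id3 and Egr1 fell, Egr1 largely through control 1. Lingo1 rose from 21.7 ± 0.194 to 36.2 ± 5.43 FPKM, and Id2 from 65.0 ± 10.5 to 100.4 ± 15.6. Of the gene sums, 7 fell and 3 rose adjusted over the list alone, and none passed with no filter. The set test on transcripts did not pass (adjusted p = 0.0605). That on gene sums passed (adjusted p = 0.0251, and adjusted p = 0.532 with an estimated correlation), and was lost under median-of-ratios, TPM and quantile scaling (adjusted p = 0.0551, 0.0810 and 0.0873), with no filter (0.0832) and without cKO 1 (0.0932).

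The 7 proposed CHD7 targets were listed from knowledge of the study, so they are not independent evidence of direction. In the gene sums 6 fell. Myrf, the myelin gene regulator listed in the files as Gm98, went from 41.3 ± 3.16 to 19.9 ± 8.41 FPKM (SD, n = 2 each; log2 fold change -1.08 ± 0.19, adjusted p = 8.27e-05). Creb3l2 went from 5.49 ± 0.264 to 2.74 ± 0.669 FPKM and Sp7, known as a bone transcription factor, from 3.10 ± 0.664 to 1.41 ± 0.311. Sox10 went from 72.5 ± 19.0 to 44.2 ± 9.81 FPKM (log2 fold change -0.69 ± 0.19, adjusted p = 0.0112). Nkx2-2 fell as given above, and Mbp did not pass. With no filter none of the 7 fell, without cKO 1 only Nkx2-2 did, without control 2, 3 did, and under median-of-ratios, TPM and quantile scaling 4, 5 and 4 did. Sox10 did not pass under any of these, and Nkx2-2 did not without control 2. None of the 7 transcripts passed over all transcripts, and 5 did adjusted over the list alone. Without the mean-variance trend all 7 gene sums fell, Mbp among them, and with a replicate block 5 did.

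**Figure D2:**
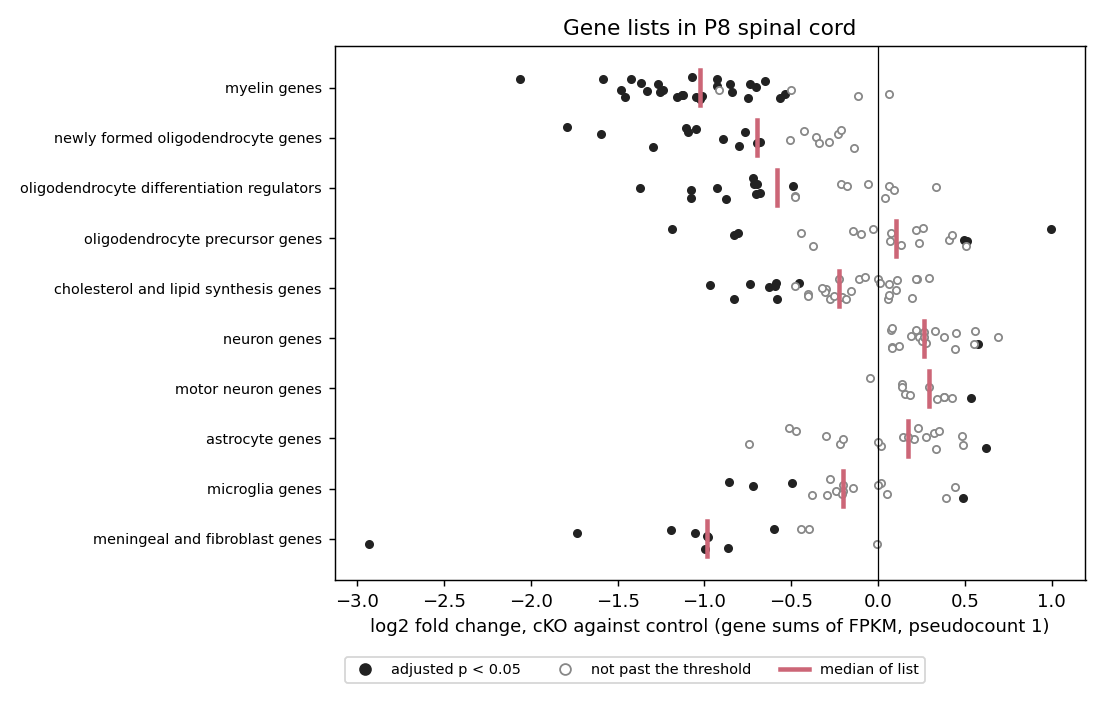
Log2 fold change (cKO against control, gene sums of FPKM with a pseudocount of 1) of each measured member of 10 gene lists, with filled points past the adjusted p threshold, open points not past it and a red bar at the median of the list. Myelin genes centre at -1.03 and meningeal and fibroblast genes at -0.98, while precursor genes centre at 0.10 and neuron genes at 0.26.

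Genes of other cell types moved less, apart from those of meninges. All 20 neuron genes lay above 0 with all libraries, with a median of 0.26 in the gene sums, and Slc32a1, the vesicular GABA transporter, was the member that rose (53.5 ± 5.34 to 81.3 ± 20.1 FPKM, SD, n = 2 each). Tubb3 and Rbfox3 had log2 fold changes of 0.69 ± 0.24 and 0.45 ± 0.16 and did not pass. Of 11 motor neuron genes, 10 lay above 0, and Slc18a3, the vesicular acetylcholine transporter, rose from 15.1 ± 2.53 to 22.1 ± 1.06 FPKM. Camera on transcripts called both lists higher (adjusted p = 1.84e-04 and 0.00572), and neither call held with an estimated correlation (adjusted p = 0.601 for each). Without control 2, no neuron gene sum rose and 1 fell, the median was 0.16, and the set test on gene sums did not pass (adjusted p = 0.161). No neuron gene sum rose adjusted over the list alone, and Slc18a3 did. Slc1a3, a glutamate transporter, was the 1 of 19 astrocyte genes that rose (52.9 ± 6.001 to 81.6 ± 2.04 FPKM), also adjusted over the list alone, and the list was not called (adjusted p = 0.271). Among 17 microglia genes, Tmem119, P2ry12 and Cx3cr1 fell and C1qb rose, and the list was not called (adjusted p = 0.201). Adjusted over the list alone, 3 microglia genes fell and 3 rose. None of 17 vascular genes passed, also adjusted over the list alone (median -0.06, list adjusted p = 0.716).

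Of 33 measured genes of cholesterol and lipid synthesis, 8 fell and none rose, with a median of -0.23, and the counts adjusted over the list alone were the same. Elovl1, an elongase of very long fatty acids, went from 60.5 ± 9.32 to 30.6 ± 6.61 FPKM (SD, n = 2 each; log2 fold change -0.97 ± 0.18, adjusted p = 1.57e-04). Elovl6 and Ebp fell by 0.59 and 0.46 on the log2 scale. Camera on transcripts called the list lower (adjusted p = 0.00929), which was lost with an estimated correlation (adjusted p = 0.700), without cKO 1 (adjusted p = 0.301) and without control 2 (adjusted p = 0.156). Of the gene sums, 3 fell under median-of-ratios and under TPM scaling, 4 under quantile scaling and without control 1, 5 without control 2, 1 without cKO 1 and none with no filter.

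Among 21 cell cycle genes, Mcm6 and Rrm2 rose, by 0.93 and 0.55 on the log2 scale, also adjusted over the list alone, and the list was not called on transcripts (adjusted p = 0.138). On gene sums camera called this list higher (adjusted p = 0.0459), also under quantile scaling (adjusted p = 0.00402). That call was lost under median-of-ratios and TPM scaling (adjusted p = 0.0519 and 0.0715), with no filter (0.0556) and with an estimated correlation (0.532). Cdkn1a, a cell cycle inhibitor, rose from 7.99 ± 1.07 to 18.4 ± 1.06 FPKM (SD, n = 2 each; log2 fold change 1.11 ± 0.15, adjusted p = 1.96e-06) and was the 1 of 16 p53 targets that passed, also adjusted over the list alone (list adjusted p = 0.547). None of the 17 CHD and SWI/SNF remodeler genes passed, also adjusted over the list alone (list adjusted p = 0.835). Of 12 genes of the Wnt and BMP response, Smad7 and Id3 fell and Id2 rose (list adjusted p = 0.167), and adjusted over the list alone 3 fell and 1 rose. By fry, a rotation test run beside camera, these Wnt and BMP genes were the 1 list to pass on gene sums (adjusted p = 0.00603), myelin genes did not (adjusted p = 0.196), and on transcripts no list passed (lowest adjusted p = 0.137). Of 11 immediate-early and stress genes, Arc fell by 1.03 on the log2 scale and Egr1 also fell, and the list was lower by camera (adjusted p = 0.0326). That call was lost with an estimated correlation (adjusted p = 0.601) and without control 1, cKO 1 or cKO 2. Egr1 was at 16.2 and 5.90 FPKM in controls 1 and 2 and at 4.21 and 4.62 FPKM in cKO 1 and 2, so its fall rests largely on control 1, without which 1 gene of the list fell. Of these genes, 3 fell adjusted over the list alone. Of 9 inflammation and reactive glia genes, Serpina3n and Cd44 fell (list adjusted p = 0.835), and 3 did adjusted over the list alone. Of 7 ependymal genes, Ccdc153 and Tmem212 rose and Rsph1 fell, also adjusted over the list alone (list adjusted p = 0.339). Of 5 sensory ganglion genes, Pou4f1 rose, also adjusted over the list alone (list adjusted p = 0.105). Pvalb and Acta1, the 2 measured skeletal muscle genes, did not pass over all genes and each passed adjusted over the list alone, in opposite directions. With no filter, none of the gene sums named in this paragraph and in the paragraph on other cell types passed. Apart from Cdkn1a, each list of these paragraphs with calls lost at least 1 of them under another scaling or without 1 library, and none of the inflammation genes fell under any of the 3 scalings. Mitochondrial genome genes were not analysed here.

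The libraries of a group differed in markers of tissue around the cord. Of 12 genes of meninges and fibroblasts, 9 fell and none rose, with a median of -0.98, and 11 fell adjusted over the list alone. Ptgds was at 161 and 16.2 FPKM in controls 1 and 2 and at 4.57 and 7.54 FPKM in cKO 1 and 2. Without control 1, 3 of these genes fell, and the median was -0.43. Under median-of-ratios, TPM and quantile scaling 5, 2 and 1 fell, with robust moderation 2, and with no filter none. Camera on transcripts called the list lower (adjusted p = 6.19e-04), and with an estimated correlation it did not pass (adjusted p = 0.663). Among 11 Schwann cell genes, 3 fell, with Cdh19 and Pmp22 among them, and Ngfr, L1cam and Sostdc1 rose, and 3 fell and 4 rose adjusted over the list alone (list adjusted p = 0.716). Without control 1, or with robust moderation, 1 of the Schwann cell genes fell, and without control 2 or without cKO 1 none rose. Cdh19 was at 2.30 and 2.35 FPKM in the controls and 0.25 and 0.34 FPKM in the cKO libraries. With robust moderation or with no filter, Ptgds did not pass. Of 8 blood cell genes, 3 rose (Hba-a1, S100a8, S100a9) and 3 fell (Hba-a2, Alas2, Hbb-b1), also adjusted over the list alone (list adjusted p = 0.305). With no filter none of the blood cell genes rose, without cKO 1 S100a8 and S100a9 did not pass (adjusted p = 0.0525 and 0.109), and Hba-a1 did not with robust moderation. None of the blood cell genes fell without control 2, under any of the 3 scalings, with robust moderation or with no filter. Hba-a2 was at 86.7 FPKM in control 2 and at 0.99, 2.04 and 0.58 FPKM in control 1, cKO 1 and cKO 2, and near-identical hemoglobin genes share reads.

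Sex-linked transcripts differed between the libraries. Xist, expressed from the inactive X chromosome of females, was at 55.6 and 51.8 FPKM in the controls, 19.6 FPKM in cKO 1 and 0.23 FPKM in cKO 2. The Y-linked genes were near the floor in the controls and in cKO 1 and present in cKO 2, where Ddx3y was at 11.6, Eif2s3y at 20.4, Kdm5d at 3.80 and Uty at 2.23 FPKM. Their highest value in the other 3 libraries was 0.35 FPKM. Sex therefore differs between libraries and is not balanced over the groups.

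Hox genes, whose expressed set follows the position along the body axis, were looked at after their values were seen. The 7 measured genes of paralog groups 10 to 12 all had both cKO libraries above both controls, with a median log2 fold change of 0.56, and 5 of them rose. Over all 12913 genes tested, 3132 had both cKO libraries above both controls. The 24 genes of groups 2 to 9 had a median of 0.12, with 2 rising (Hoxb7, Hoxc9) and 1 falling (Hoxd3). Hoxd11 went from 1.997 ± 0.1001 to 6.53 ± 1.72 FPKM (SD, n = 2 each; log2 fold change 1.31 ± 0.16, adjusted p = 2.42e-07), and Hoxc12 from 0.20 ± 0.0841 to 2.79 ± 2.06 FPKM. The median of groups 10 to 12 relative to the control mean was 0.79 in cKO 1 and 0.34 in cKO 2. The myelin difference was also larger in cKO 1, but so was the distance from the controls over all genes. The order of 2 libraries cannot show a relation between them. Under median-of-ratios, TPM and quantile scaling the median of the posterior genes stayed between 0.58 and 0.69, with 4, 3 and 3 of them rising. Without cKO 1 the median was 0.34 and 1 gene rose.

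**Figure D3:**
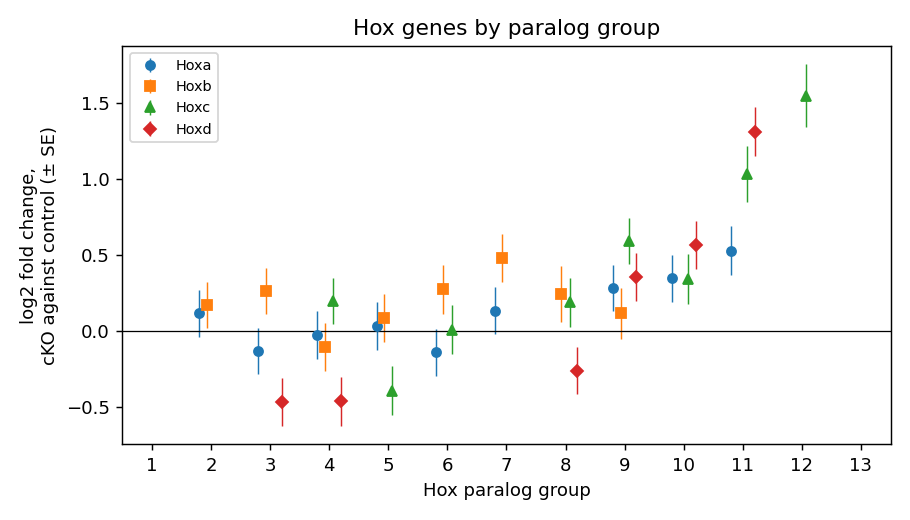
Log2 fold change (cKO against control, gene sums, bars ± SE) of 31 measured Hox genes against their paralog group, with a marker for each of the 4 clusters. Genes of groups 2 to 9 scatter around a median of 0.12, and the 7 genes of groups 10 to 12 lie between 0.34 and 1.55.

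Over all transcripts, 11 of 15494 were higher and 9 lower in cKO in the limma fit, and 13 of these 20 were under 300 bases, among them 12 microRNA and small nucleolar RNA transcripts. At an unadjusted p under 0.05, 981 were higher and 1330 lower. Under quantile scaling 8 were higher and 4 lower. Leaving out 1 library at a time gave 22 to 51 higher and 3 to 40 lower. By the size rule, 571 transcripts were higher and 861 lower, 1432 in all, against 409 and 460 in the 2 other splits of the libraries. Summing every transcript of a gene gave 23 genes higher and 30 lower, and the transcripts of at least 300 bases alone gave 5 higher and 13 lower. In the gene sums used here, 533 of 12913 genes rose and 845 fell. This fit was adopted after its larger count had been seen. With no filter on low values it gave 22 rising and 33 falling, and without cKO 1, 107 rising and 277 falling.

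Of the named transcripts, Olfm1 NM_001038612 was higher and BC002163, AI506816, Arhgef2 NM_001198912, Hddc3 and Neat1 were lower past the threshold. BC002163 (chromosome 16) went from 44.9 ± 10.8 to 0.50 ± 0.108 FPKM (SD, n = 2 each; transcript adjusted p = 0.00802). Hddc3 (chromosome 7) went from 30.6 ± 2.66 to 6.12 ± 0.558 FPKM, and Neat1, a long noncoding RNA of nuclear paraspeckles, from 13.3 ± 0.461 to 3.39 ± 0.0365 FPKM. For Olfm1 and Arhgef2, the value given to the isoform changed more than the gene sum did. Isoforms of a gene share reads, so the split between them is uncertain and a change of isoform was not tested. The Olfm1 isoform went from 0.28 ± 0.0294 to 21.3 ± 2.02 FPKM, and the sum over its transcripts had a log2 fold change of 0.65 ± 0.20. The Arhgef2 isoform went from 4.40 ± 0.195 to 0.0030 ± 0.00303 FPKM, and its gene sum fell by 0.68 on the log2 scale. Each of these 6 calls was lost without at least 1 library and with no filter on low values.

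Among those filled up by the size rule and not past the threshold on transcripts were Dynlt1b, Spast, Txnl4a, Tmem181b-ps, Orc6, Egfl6, Hist1h1c, Cdkn1a, Nudt19 and Arrdc4, all higher, and Hiatl1, Gdpd3, Lima1, Rtn4, Clk1, Spp1 and Gpr17, all lower. These are single transcripts, and for Spast, Txnl4a, Orc6, Rtn4, Clk1 and Spp1 another transcript of the gene had a fold change in the other direction. For Spp1, the lower transcript was NM_001204203, and NM_009263 had a log2 fold change of 0.92 (transcript adjusted p = 0.252). The gene sums rose for Dynlt1b, Tmem181b-ps, Egfl6, Hist1h1c, Cdkn1a, Nudt19 and Arrdc4 and fell for Hiatl1, Gdpd3, Lima1, Clk1 and Gpr17. The gene sums of Spast, Txnl4a, Orc6, Rtn4 and Spp1 did not pass. Dynlt1b and Tmem181b-ps lie on chromosome 17 and have near-identical copies that can share reads, so their values are uncertain.

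By the same ranking on gene sums, the genes that rose most were Dynlt1b, Eif2s3y, Ddx3y, Mid1, Hoxc12, Hba-a1, Ccl12, Rec8, Hist1h1c, Hoxd11, Errfi1 and Fxyd2. Among those that fell most were BC002163, Xist, Ptgds, Hddc3, AI506816, Opalin, Gdpd3, Mfap4, Pcdhgb8, H2-Bl and Col1a1. Mid1, an X-linked ubiquitin ligase gene, rose from 5.84 ± 2.61 to 20.1 ± 0.533 FPKM (SD, n = 2 each; log2 fold change 1.68 ± 0.18, adjusted p = 7.75e-09). Gdpd3 fell from 4.92 ± 0.302 to 0.59 ± 0.0596 FPKM. Rec8, a cohesin subunit of meiosis, rose from 0.22 ± 0.0498 to 2.11 ± 0.176 FPKM. Ccl12 did not pass without cKO 2 (adjusted p = 0.0634). Without cKO 2, Eif2s3y and Ddx3y were too low to be tested. Xist, Ptgds, Mfap4, Col1a1, Hba-a1, Hoxc12, Ccl12, Eif2s3y and Ddx3y, whose values differ widely within a group, did not pass with robust moderation or with no filter, and Mid1, Hoxd11, Errfi1 and Fxyd2 did not pass with no filter.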

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

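The crossed block and the fits restricted to transcripts of at least 300 bases, with all alternatives run on them, were chosen only after the results were seen. For the 24 genes ranked by gene sums, the alternatives kept the direction, and 308 values also kept their side of the threshold while 36 did not. The ranking took only genes whose groups did not overlap, so leaving out a library could not turn their direction. Other moderation and the blocks leave the fold change as it is. The kept direction is therefore largely fixed by the selection. Outside this ranking, Hba-a2 did not keep its direction without control replicate 2. Of the medians of gene lists compared with the transcript fit, 352 kept direction and side, and 2 turned with a call in the alternative. For 16 more, with no call in either fit, the sign changed or the median became 0. The comparisons with other moderation could not differ, since moderation alters neither the median of a list nor the camera test. In the gene sums, the medians of blood cell, inflammation, microglia, remodeler, Schwann cell, ependymal and vascular genes changed sign under at least 1 alternative. The 2 turned medians were both for the median log2 fold change, blood cell genes, which was 0.092 with no filter on low values, and ran from -0.70 without control replicate 1 to 0.80 without control replicate 2, against -0.19 with all libraries. The cause was not tested. With the estimated correlation the medians of myelin genes (-1.02), newly formed oligodendrocyte genes (-0.77) and differentiation regulators (-0.49) stayed. Their camera calls were lost (adjusted p = 0.601). The camera p of Wnt and BMP response genes also rose, from 0.0909 to 0.217, although their estimated correlation of -0.062 lay below the preset 0.01. Lost calls thus do not rest on correlation alone, as estimating it leaves camera 2 residual degrees of freedom. The Chd7 level, as a log2 fold change, ran from -0.29 without cKO replicate 2 to 0.023 without cKO replicate 1, and Chd7 has no value with a mean FPKM of at least 5.

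In the limma fit there were 11 transcripts higher in cKO and 9 transcripts lower in cKO. There were 7 higher with a pseudocount of 5, 1 higher and 0 lower with no filter, 14 lower with a mean FPKM of at least 5, 5 lower with median-of-ratios scaling, 4 lower with quantile scaling, 21 higher and 30 lower with robust moderation, 18 and 21 at an adjusted p under 0.1, 23 and 30 with all transcripts summed by gene, 5 higher for transcripts of at least 300 bases, and 533 and 845 for gene sums of these. Leaving out a library gave 22 to 51 higher and 3 to 40 lower. The cause was not tested. The real split of the 4 libraries gave 20 transcript calls and the highest of the 2 other splits 13, and 3 splits are too few for a share under 0.05.

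There were 533 genes (sums of transcripts of 300 bases or more) higher in cKO and 845 genes (sums of transcripts of 300 bases or more) lower in cKO. There were 22 and 33 with no filter, where the prior degrees of freedom of the spread were 4.11 instead of 36.3, 552 lower with median-of-ratios scaling, 199 and 446 with TPM scaling, 310 and 426 with quantile scaling, and 832 higher at an adjusted p under 0.1. Leaving out a library gave 107 to 555 higher and 277 to 900 lower, with the lone library taken to vary like the other group.

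There were 571 transcripts higher in cKO by the size rule and 861 transcripts lower in cKO by the size rule. There were 872 higher with a pseudocount of 0.1, 199 and 342 with a pseudocount of 5, 316 and 454 with a mean FPKM of at least 5, 172 and 271 at 2-fold, 283 and 562 with all transcripts summed by gene, and 260 and 533 for gene sums of transcripts of at least 300 bases, where fewer items are tested. Leaving out a library gave 564 to 1105 higher and 829 to 1276 lower.

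The labels give replicate numbers and no pairing. Deviations from the group means of same-numbered libraries correlated at -0.241 over genes. With a replicate block, the count of transcripts higher in cKO was 8 and of transcripts lower in cKO 4, and that of genes (sums of transcripts of 300 bases or more) higher in cKO was 351 and of genes (sums of transcripts of 300 bases or more) lower in cKO 645. With the numbers crossed, these counts were 1, 0, 943 and 1235. The planned count of genes beyond the Cufflinks intervals was not run, as the columns used here hold no bounds. Control 2, at 582 megabases of coverage, limits what the shallowest library can show for low transcripts.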

Other observations

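The test of the chromosome around Chd7 was set out before its result was seen, and the other tests of explanations in this part were chosen after the patterns were seen. All of them use the gene sums unless transcripts are named.

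The genes in this paragraph were chosen after their values were seen. Of the Neat1 neighbourhood on chromosome 19, Malat1, Slc25a45 and Cdc42ep2 lay lower with Neat1, while Cnih2 lay higher. S100a8 and S100a9, calcium-binding proteins of neutrophils, rose from 0.84 ± 0.0903 and 0.78 ± 0.507 FPKM to 2.66 ± 0.927 and 2.55 ± 1.18 FPKM (SD, n = 2 each), and neither passed without cKO 1 (adjusted p = 0.0525 and 0.109) or with no filter. Among the microglia genes, the receptor genes P2ry12 and Cx3cr1 fell (log2 fold changes -0.72 ± 0.15 and -0.50 ± 0.15) while C1qb rose (0.49 ± 0.15), and all were beyond the control libraries in both cKO libraries. Across the Pcdh gene clusters on chromosome 18, Pcdha7, Pcdhga9 and Pcdhgc4 were higher and Pcdhb6, Pcdhb7, Pcdhga5 and Pcdhgb8 lower by at least 1.5-fold, with shared exons in the Pcdha and Pcdhg clusters that leave the split between their transcripts uncertain.

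Myelin genes were lower in cKO cords while precursor genes were not. A loss of the whole oligodendrocyte lineage would lower both lists alike. The precursor median exceeded the myelin median by 1.13 on the log2 scale (95% bootstrap interval over genes, which are not independent replicates, 0.829 to 1.41). This argues against such a loss as the only cause. A smaller loss stays open. Of 20 differentiation regulators 11 fell and none rose, with Olig1, Olig2 and Sox10 at -0.88, -0.70 and -0.69. Of the precursor genes 3 rose and 3 fell, and whether other cell types express them was not tested. Log2 fold changes fell with transcript length over all genes (Spearman -0.17), and after this trend was removed the myelin median was still -1.01 (interval -1.16 to -0.875). A more caudal sampling of the cKO cords stays open, since Hox genes of groups 10 and above exceeded the others by 0.45 (interval 0.197 to 1.27), and the cord at this age may carry less myelin toward its tail, which these data do not test. A change in oligodendrocyte differentiation in the cKO, a sex difference between the libraries and a difference in age within the day were not separated from this.

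Changed genes may lie close to each other where the groups carry different stretches of chromosome, a possibility raised by the mixed background and by neighbours such as Dynlt1a, Dynlt1b, Tmem181a and Tmem181b-ps on chromosome 17. Among genes called with at least 1.5-fold change, 332 neighbouring pairs started within 1 megabase of each other, and shuffled calls gave a mean of 336 (middle 95% from 313 to 360), so no excess of close pairs was seen, and a count within this range leaves such stretches open. Within 20 megabases of Chd7, 3 of 60 genes were called (5%), against 6.19% elsewhere (Fisher's exact test, two-sided, p = 1). The interval of that share, 1.04% to 13.9%, covers the share elsewhere, and the controls carry 1 floxed allele too, so a stretch carried along with that allele stays open. Single loci such as BC002163, Hddc3 and H2-Bl were not tested, and a strain variant stays open for them.

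Short RNAs made up most of the transcript calls. Transcripts under 300 bases had a median standard deviation within groups of 2.46 on the log2 scale, 15.5 times that of longer transcripts with the same mean FPKM (interval 13.3 to 18.2). Few reads scaled up by a short length may give such values, and their calls may be chance agreements within pairs of libraries. No biological explanation was tested for them.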
